A study of Mus musculus with 9 samples.

How the data were processed

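C1498 is a mouse acute myeloid leukaemia cell line. Per the labels' protocols, cells were infected with lentivirus carrying GFP and either a hairpin against Zeb1 (sequence C or D) or a negative control construct (Scr), GFP-positive cells were isolated 2 weeks later, and biotin-labelled total RNA was hybridised to 1-colour Affymetrix-type arrays. There were 9 arrays, 3 in each of 3 groups. The labels do not say whether the arrays of a group came from separate infections, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision.

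The submitters' processing notes name RMA and the Transcriptome Analysis Console, without versions. The values the authors deposited were linear RMA signals, 2 to the power of a log2 value with 2 decimals, written without their decimal point. Each of the 199854 cells was returned to its log2 value by choosing the place of the decimal point that makes the log2 value a multiple of its last decimal, within a tolerance of 1e-06 steps. The farthest accepted value lay 9.1e-13 steps away and the nearest rejected place 0.036 steps. The recovered log2 values ran from 3.26 to 17.44, no pair of arrays held identical columns, and Pearson's r across probe sets was 0.9777 to 0.9949 within groups and 0.9684 to 0.9889 between groups.

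Of the 22206 probe sets, 19572 had 1 gene symbol in the platform annotation, 0 had several, and 2634 are unnamed here and were not tested. Symbols were looked up by gene identifier in a RefSeq table of assembly GRCm38.p6, which also gave the order of neighbouring genes. No coordinates are given, because the build behind the files is not given in the sources used here. Zeb2 was not analysed here.

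Each probe set was tested with limma 3.58.1 in R 4.3.3, on log2 values, with a mean per group, all 9 arrays in the fit, empirical Bayes moderation and Benjamini-Hochberg adjustment within each comparison. A gene was called at an adjusted p under 0.05. The comparisons were shZeb1_C against Scr, shZeb1_D against Scr, the mean of both hairpins against Scr, and shZeb1_D against shZeb1_C. Adjustment over a list alone used only the members of that list. The 29 gene lists, fixed before the data were examined, were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The tests, the other settings tried, except those given as later choices, and the rule for named genes were fixed then too. Other settings covered dim probe sets, normalization, the variance prior, array weights, thresholds, probe sets per gene, the arrays in the fit and leaving out each array in turn. The rule took Zeb1 and a fixed set of genes, and for each pairwise comparison up to 10 rises and 10 falls with the largest fold change among called genes whose 3 arrays in 1 group all lay beyond the 3 of the other, with the higher mean above the median level of 7.10. Chance alone separates 3 arrays from 3 for 10% of genes. It also took up to 10 genes per direction called for both hairpins, ranked by the smaller change, and up to 4 called members per list. Predicted genes and olfactory, vomeronasal, micro-RNA and snoRNA genes were not named.

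Blocks of neighbouring genes were sought after the data had been examined, in 9756 genes above the median level on chromosomes 1 to 19 and X. A running median over 51 genes had to pass the highest of 200 shuffled gene orders, runs up to 25 genes apart were joined, and blocks needed 40 genes and a median shift of 0.3. These limits were also set after the data had been examined, so the share of called genes inside blocks was counted again under a looser rule, used in the first scan, of 20 genes, a threshold at percentile 95 of the shuffled orders, no joining and no minimum shift. The arrays also fell into sets of 5 and 4 by the sign of the first principal component of within-group residuals. As these sets were taken from the values, they served only as a covariate or to hold arrays out. A comparison between the sets had been run during exploration, and is not reported because it tests groups defined by their own values. Tests of blocks on the arrays that had defined them were likewise replaced by tests on held-out arrays. A ratio of the fold changes of the hairpins was also set aside as void, because it used the 42 genes selected for changing with both: its median was 1.11 there, but 0.53 over all genes called in shZeb1_D, against 0.19 for Zeb1. Its replacement, the share of genes called in shZeb1_C that the comparison of the hairpins called back (34.6%), used the shZeb1_C arrays to select and to test, and gave way to a test on held-out arrays. Block shares of the shared rises and of the shared falls apart were computed and dropped as void. This was because every stretch found as a block with both hairpins had shifted down.

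The steps were tested on simulated data for shZeb1_C against Scr, with 19572 probe sets and 200 changed genes in each of 5 runs. Changes of 0.5, 1 and 2 on the log2 scale were recovered for 1.19%, 37.6% and 89.4% of genes, and 23 of 448 calls were false. A planted list shift and a planted block, each of 0.5, were found in 5 of 5 runs, with 0 other lists and 0 other blocks. The simulated noise was independent between genes and arrays, unlike that of the real arrays. These counts therefore do not show how often correlated genes give false calls, lists or blocks.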

Results

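Gene expression was measured in GFP-positive C1498 mouse leukaemia cells carrying a control construct (Scr) or a short hairpin RNA against Zeb1, a zinc-finger transcription factor known for its role in epithelial-mesenchymal transition. The hairpins were called shZeb1_C and shZeb1_D, and each group had 3 arrays. Array medians lay between 6.97 and 7.16 (log2). According to the title of the series, the study asked how Zeb1 in leukaemia cells acts on T cells and Th17 cells.

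Zeb1, on chromosome 18, was lower with hairpin D but was little changed in the arrays labelled shZeb1_C. Its log2 expression was 10.46 ± 0.15 (SD, n = 3) in Scr, 10.25 ± 0.21 in shZeb1_C and 9.41 ± 0.15 in shZeb1_D. In shZeb1_D it stood at 48.3% of Scr, a log2 fold change of -1.05 ± 0.16 (SE) with an adjusted p of 0.0263 in limma. In shZeb1_C it stood at 86.8% of Scr, a log2 fold change of -0.20 ± 0.16 that did not pass the test (limma adjusted p = 0.895). The difference between the hairpins, -0.85 ± 0.16, also missed the threshold (limma adjusted p = 0.056). Exact two-sided permutation tests gave p = 0.10 for shZeb1_D and 0.30 for shZeb1_C, and 0.10 is the smallest p that 3 arrays against 3 allow. The call in shZeb1_D was lost without Scr replicate 7 (adjusted p = 0.0941), 8 (0.0502) or 9 (0.157) and without shZeb1_D replicate 14 (0.0835) or 15 (0.123), while the fold change stayed between -1.13 and -0.98.

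**Figure D1:**
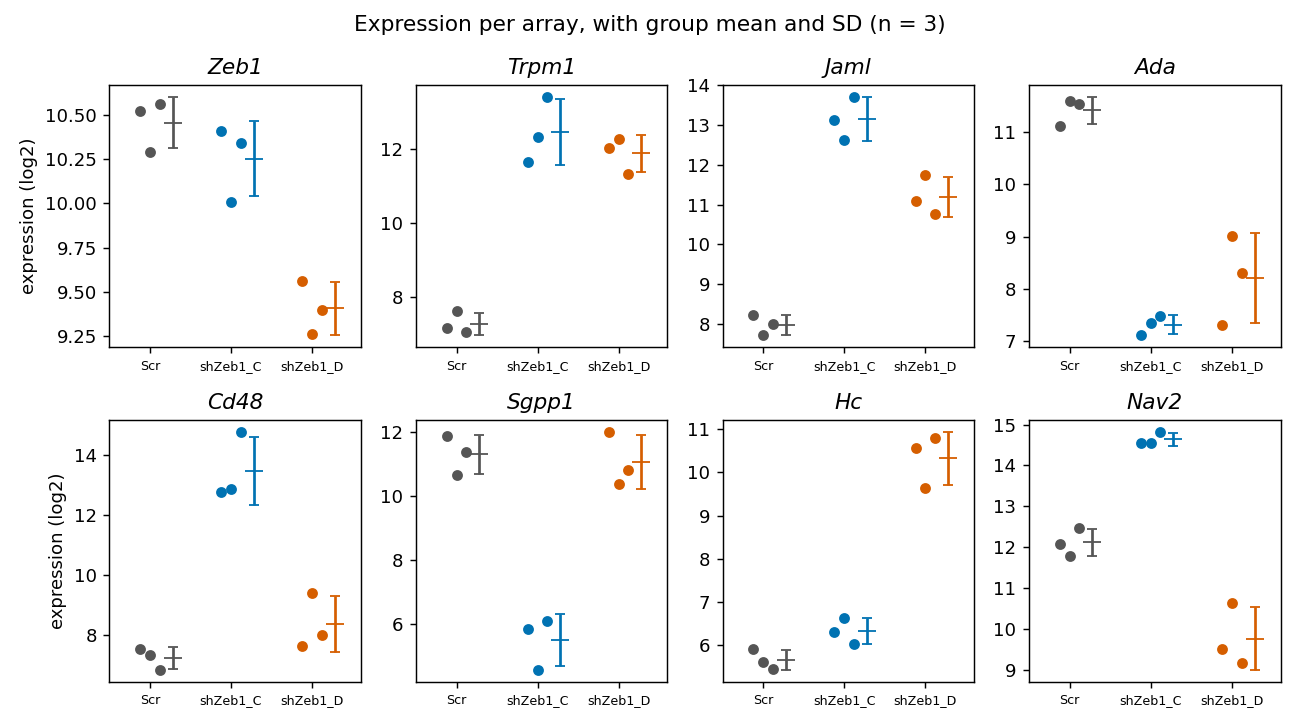
Expression (log2) of 8 genes on each array, by group, with the group mean and SD (n = 3) beside the points; the vertical axes differ and do not start at 0. Zeb1 is lower in shZeb1_D, Trpm1 and Jaml are higher and Ada lower with both hairpins, Cd48 and Sgpp1 change in shZeb1_C, Hc in shZeb1_D, and Nav2 lies on opposite sides of Scr.

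Among the named genes of shZeb1_C against Scr, Cd48 had the largest rise and Sgpp1 the largest fall. Cd48, a ligand on leukocytes, rose by 6.24 ± 0.59 on the log2 scale (SE; limma adjusted p = 0.00175), and Nkg7 and Gzmb, genes of cytotoxic granules, rose by 5.93 ± 0.80 and 4.33 ± 0.59. Gcnt2, Trpm1, Jaml, Ifitm2, Ctla2a, Arnt2 and Abi3bp rose by 4.45 to 5.33. Sgpp1, which dephosphorylates sphingosine-1-phosphate, fell by 5.81 ± 0.52, Fcgr3, an Fc receptor of myeloid cells, fell by 4.10 ± 0.19, and Ada, adenosine deaminase, fell by 4.09 ± 0.37. Plcd3, Syne4, Fam122a, Sgms1, Spock2, Pkig and Tnfrsf19 had log2 fold changes of -3.90 to -1.97. Each of these genes was separated from Scr in 3 of 3 arrays, as the naming rule required. Sgpp1, Ada, Pkig, Fam122a and Sgms1 lie in blocks of neighbouring genes that shifted down together, Ctla2a in a block that shifted up, and Jaml rose inside a block that shifted down. Of 49 calls in this comparison for genes selected by the naming rule, 20 held whichever array was left out; those of Nkg7, Gzmb, Ifitm2, Ctla2a, Syne4, Sgms1 and Pkig were among the 29 lost at least once. In all, limma called 185 of 19572 probe sets, 129 higher and 56 lower. The count moved by more than 1.5 times without Scr replicate 7 (104), 8 (84) or 9 (43), without shZeb1_C replicate 10 (103) or 11 (92) and without shZeb1_D replicate 15 (117), and was 119 without genes in shifted blocks.

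Among the fixed lists, 8 of 54 measured interferon-stimulated genes rose in shZeb1_C and 0 fell, and 14 rose when adjusted over the list alone. Gbp4, an interferon-induced GTPase, rose by 3.39 ± 0.20 and Ddx58, the RNA sensor RIG-I, by 2.09 ± 0.18, with Gbp7 at 2.00 and Gbp3 at 1.94. The list was higher by camera (adjusted p = 1.4e-11), with adjusted p = 0.174 with an estimated correlation. Of 35 T and NK cell genes 6 rose and 0 fell, and 10 rose when adjusted over the list alone. Besides Nkg7 and Gzmb they included Klrc1 (3.02 ± 0.44), an NK cell receptor, and Pdcd1 (2.64 ± 0.45), the receptor PD-1. Of the 35, 20 lay above the median level of all probe sets. On shZeb1_C replicates 10, 11 and 12 Nkg7 stood at 9.11, 9.79 and 12.65. The camera adjusted p was 4.1e-04, and the adjusted p = 0.342 with an estimated correlation. Of 23 genes of MHC class I presentation 2 rose, Erap1 by 1.24 ± 0.17 and H2-T10 by 1.47 ± 0.24, and 3 when adjusted over the list alone (camera adjusted p = 3.8e-06, and adjusted p = 0.123 with an estimated correlation). Of 42 mitosis genes 2 fell, with log2 fold changes of -1.32 for Aurka and -1.41 for Kif20b, and 7 when adjusted over the list alone (camera adjusted p = 3.8e-06, and adjusted p = 0.386 with an estimated correlation); both lie in blocks that shifted down, and the adjusted p was 0.00149 without block genes. Camera called 9 lists, 5 higher and 4 lower, against 0 with an estimated correlation, where 4 had an unadjusted p under 0.05, and 4 with fry. The 4 included erythroid, megakaryocyte and mast cell genes (fry adjusted p = 0.0216), a list with 0 of 21 members called that camera did not call.

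In shZeb1_D against Scr, Serpinb5, a serpin, rose by 4.77 ± 0.52 (SE; limma adjusted p = 0.0081) and Hc, complement component C5, rose by 4.66 ± 0.30. Trpm1, Mndal, Amy1, Jaml, Galnt3, Ldhd, Fam185a and Ppp3cc rose by 2.73 to 4.60. Cln8 fell by 4.42 ± 0.78 and Atp8b4, a phospholipid flippase, fell by 4.33 ± 0.52. Ncoa7, Ada, Dock8, Gimap6, Selplg, H2al1e, H2al1a and H2al1f had log2 fold changes of -3.36 to -2.67. As the naming rule required, each of these genes was separated from Scr in 3 of 3 arrays. H2al1a and H2al1f had equal values, so they are not counted as separate evidence. Amy1 and Fam185a lie in blocks that shifted up and Ada in a block that shifted down, while Jaml rose inside a block that shifted down. Selplg, the selectin ligand PSGL-1, fell by 2.95 ± 0.43. Tnf, an inflammatory cytokine, fell by 2.10 ± 0.35 and Il4ra, an interleukin-4 receptor chain, fell by 2.42 ± 0.34. Of 44 calls in this comparison for genes selected by the rule, besides Zeb1, only those of Trpm1, Jaml, Plcd3, Hc, Amy1, Abcb1a, Gbp7 and Zfp64 (8) held whichever array was left out, and 36 were lost at least once. In all 165 probe sets were called, 78 higher and 87 lower, a balance that turned to 81 and 74 after quantile normalizing again and is not firm. The count fell to 14 without Scr replicate 9 and 17 without shZeb1_D replicate 15; it was 58 and 87 without Scr replicates 7 and 8, 80 without shZeb1_D replicate 14, 93 and 103 without shZeb1_C replicates 10 and 11, and 67 without genes in shifted blocks.

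Of the 54 interferon-stimulated genes 3 rose in shZeb1_D and 0 fell, Gbp7 by 1.74, Gbp4 by 1.40 and Gbp3 by 1.35, and 4 rose when adjusted over the list alone. Gbp7 and Gbp3 lie in a block that shifted up in shZeb1_D (list: camera adjusted p = 0.00112, and adjusted p = 0.347 with an estimated correlation). Of 42 mitosis genes Aurka fell by 1.75 ± 0.22, and 2 fell when adjusted over the list alone (camera adjusted p = 3.7e-05, and adjusted p = 0.341 with an estimated correlation). Of 14 Zeb1 partner genes Zeb1 itself and Smarca4 fell, the latter with a log2 fold change of -0.95 ± 0.14 and inside a block that shifted down; 2 fell when adjusted over the list alone (camera adjusted p = 0.0322, and adjusted p = 0.341 with an estimated correlation). The call of this list was also lost without block genes (adjusted p = 0.0564) and with the array sets as a covariate (adjusted p = 0.0905). As the list includes Zeb1, the target of the hairpin, part of its fall is built in. Camera called 11 lists, 2 higher and 9 lower, against 0 with an estimated correlation, where 2 had an unadjusted p under 0.05, and 3 with fry. Those 3 were Zeb1 partners and JAK-STAT genes (fry adjusted p = 0.0423 for both) and erythroid, megakaryocyte and mast cell genes (fry adjusted p = 0.00803). Camera did not call the last.

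Several genes tied to the question of the series did not pass the test against Scr with either hairpin. Arg1, arginase 1, averaged 11.35 ± 0.75 (SD, n = 3) in Scr, 8.85 ± 1.22 in shZeb1_C and 8.63 ± 1.06 in shZeb1_D, with limma adjusted p of 0.192 and 0.132. Tgfb1 had log2 fold changes of -0.37 ± 0.28 (SE) and -1.24 ± 0.28, with adjusted p of 0.885 and 0.104. Il6, Il23a, Mmp9, Cd274, Socs2, Arg2, Cdh1, Vim, Cxcr4, Kit and Myc had log2 fold changes between -0.29 and 0.50. Of the 24 Th17-related cytokine genes measured, 0 were called in shZeb1_C and 1, Tnf, in shZeb1_D, with the same counts when adjusted over the list alone. Of 38 epithelial genes Ap1m2 fell in shZeb1_C by 1.00 ± 0.14, and 0 were called in shZeb1_D; adjusted over the list alone, 1 fell with each hairpin. Camera called neither list (adjusted p of 0.876 and 0.486 for the Th17-related list and of 0.478 and 0.815 for the epithelial list). Only 5 of the 24 Th17-related and 9 of the 38 epithelial genes lay above the median level of all probe sets.

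The comparisons of both hairpins with Scr called 42 probe sets in the same direction, 24 higher and 18 lower, and 1 in opposite directions. Trpm1 rose by 5.19 ± 0.42 and 4.60 ± 0.42 (SE; limma adjusted p of 9.9e-04 and 0.00634), Jaml, an adhesion molecule, by 5.17 and 3.22, and Mndal by 3.66 and 3.30. Abcb1a and Abcb1b, drug efflux pumps, rose by 2.93 and 1.76 in shZeb1_C and by 2.52 and 1.90 in shZeb1_D. Etl4, Lrrc42, Tex19.2, Gbp7 and Mylip also rose. Abcb1a and Abcb1b lie in a block of chromosome 5 whose shift was 0.72 in shZeb1_D and 0.04 in shZeb1_C, and Ada, Pkig, Tomm34 and Zfp64 in the block of chromosome 2 that shifted down with both. Fbxl12 lies in a shifted block of chromosome 9, and Gbp7 in a block of chromosome 3 that shifted up in shZeb1_D. Ada had log2 fold changes of -4.09 and -3.20, and Plcd3, a phospholipase C, of -3.90 and -2.66, and Pkig, Spock2, Plin2, Tomm34, Fbxl12, Marveld1, Zfp64 and Agrn also fell. Independent lists of these sizes would share 0.76 genes, a figure that does not allow for the shared Scr arrays. Over all genes the fold changes of the hairpins had a covariance of 0.091, against 0.037 in simulated unchanged groups with shared controls. Their correlation (0.47 against 0.50 simulated) and the share of genes with the same sign (66.0% against 66.6%) did not exceed the simulated values. The simulated groups shared 0.00 calls, but with a mean of 0.08 and 0.07 calls per hairpin they had almost none to share, so how much of the overlap comes from the shared controls is open. With array medians subtracted the split was 17 higher and 21 lower, and without Scr replicate 7 it was 7 and 17; the count was 7 without Scr replicate 9, 24 without Scr replicate 7, 21 without Scr replicate 8, 24 and 21 without shZeb1_C replicates 10 and 11, 20 and 8 without shZeb1_D replicates 14 and 15, and 17 without genes in shifted blocks. The mean of both hairpins against Scr gave 162 calls, 91 higher and 71 lower (70 and 76 with array medians subtracted, 22 and 39 without Scr replicate 7), and 9 lists by camera, against 0 with an estimated correlation, where 2 had an unadjusted p under 0.05, and 2 with fry. That count of 162 genes was 61, 62 and 16 without Scr replicates 7, 8 and 9, 91 and 105 without shZeb1_C replicates 10 and 11, and 78 without shZeb1_D replicate 15. For the mean too, fry called the erythroid, megakaryocyte and mast cell list (fry adjusted p = 0.00919) and camera did not.

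Compared directly, 166 probe sets differed between the hairpins, 60 higher and 106 lower in shZeb1_D. Ifitm2 (-6.87 ± 0.86, SE; limma adjusted p = 0.00881), Atp8b4 (-6.04 ± 0.52), Nkg7, Cd48, Gcnt2, Aqp9, Arnt2, Nav2, Lcp2 and Klra13-ps were lower in shZeb1_D. Sgpp1 (5.57 ± 0.52), Serpinb5 (4.17 ± 0.52), Hc, Fcgr3 (3.32 ± 0.19), Fam122a, Prss12, Amy1, Syne4, Nos1ap and Fam185a were higher. Il6ra, an interleukin-6 receptor chain, differed by -2.77 ± 0.42. Of 36 calls between the hairpins for genes selected by the rule, 17 held whichever array was left out, and those of Ifitm2, Nkg7, Serpinb5 and Il6ra were among the 19 lost at least once. Of the 35 T and NK cell genes 5 were lower in shZeb1_D, and 9 were lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.00266, and adjusted p = 0.309 with an estimated correlation). Lists of MHC class I (1 of 23 members lower, Erap1; 5 when adjusted over the list alone) and JAK-STAT genes (1 of 39 lower, Il6ra; 3 when adjusted over the list alone) were lower in shZeb1_D by camera, with adjusted p of 2.3e-07 and 9.0e-05, and held with an estimated correlation (adjusted p = 0.0325 for both). Camera called 10 lists, each of them lower in shZeb1_D, and 5 had an unadjusted p under 0.05 with an estimated correlation. The count of genes was 62 and 84 without shZeb1_C replicates 10 and 11 and 49 without shZeb1_D replicate 15.

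Long runs of neighbouring genes shifted together. At the distal end of chromosome 2, from Zhx3 to Polr3k, the median shift of 129 genes was -0.68 in shZeb1_C, with 89.9% of the genes lower, and -0.66 in shZeb1_D. On chromosome 9 a run from Olfr935 to Ice2 shifted by -0.41 in shZeb1_C and -0.45 in shZeb1_D. On chromosome 5, from Fam133b to Dok7, 128 genes shifted by 0.72 in shZeb1_D and 0.04 in shZeb1_C. On chromosome 12, from Trappc12 to Sel1l, 181 genes shifted by -0.52 in shZeb1_C and -0.01 in shZeb1_D, and on chromosome 19, from Abhd17b to Pdlim1, 58 genes shifted by -0.74 and 0.03. On chromosome 13, from Cap2 to Ptch1, 93 genes shifted by 0.46 in shZeb1_C and 0.28 in shZeb1_D, found as a block only in shZeb1_C. On chromosome 3, runs of 45 and 128 genes each shifted by 0.45 in shZeb1_D, and by 0.14 and 0.12 in shZeb1_C. The largest running medians were 0.86 and 0.98 in size, against 0.31 and 0.41 for the highest of 200 shuffled gene orders. Blocks held 38 of the 185 genes called in shZeb1_C (20.5%) and 57 of the 165 called in shZeb1_D (34.5%). The blocks were found from the same fold changes, so an excess of called genes inside them is built in, and Fisher tests of it are void and not given. The 29 neighbours of Zeb1 shifted by 0.10 and -0.13.

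**Figure D2:**
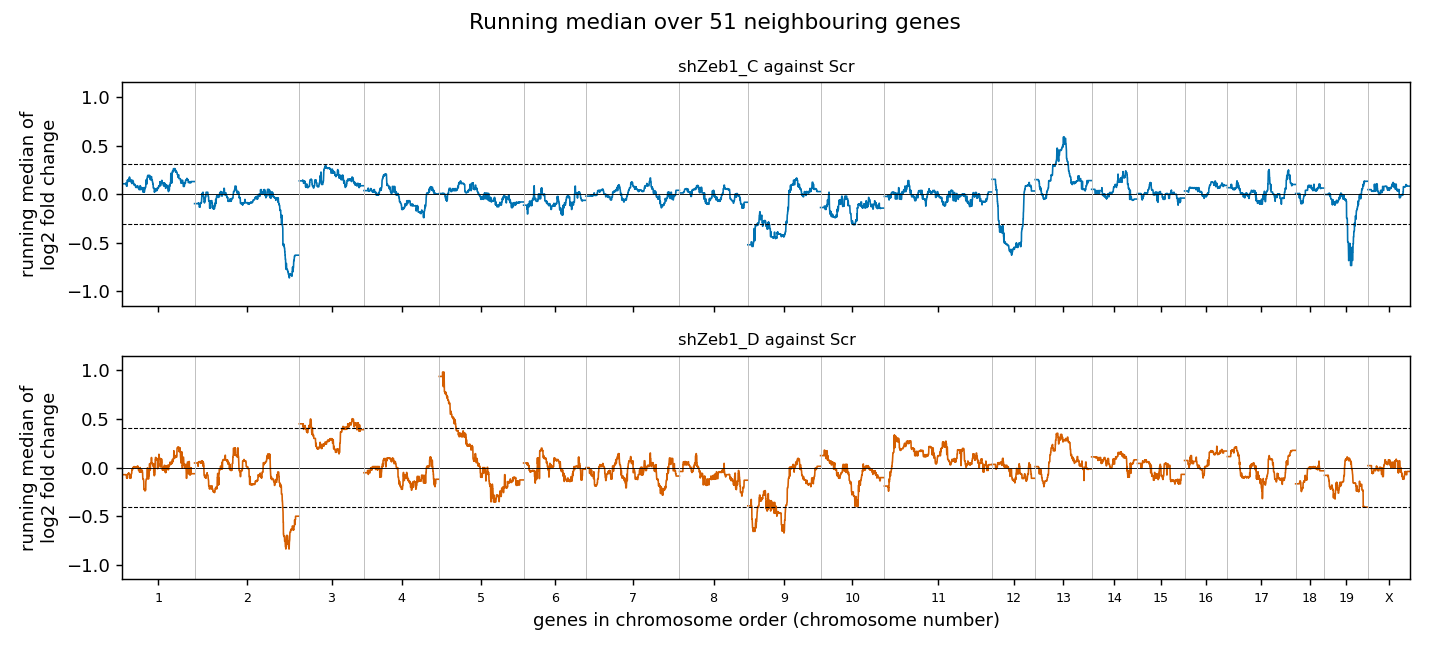
Running median of the log2 fold change against Scr over 51 neighbouring genes, in chromosome order, for each hairpin; grey lines part chromosomes and dashed lines mark the highest of 200 shuffled orders (0.31 and 0.41). Chromosomes 2 and 9 dip with both hairpins, and chromosomes 12 and 19 dip in shZeb1_C. Chromosome 13 rises in shZeb1_C, and chromosomes 3 and 5 rise in shZeb1_D.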

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

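The tests of array sets, copy number, Zeb1 proportion, normalization and signal range in this part were chosen after related results had been seen; the share of called genes inside blocks, the block share of all shared calls and the counts over other splits were planned before theirs.

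The hairpins differed from each other, by a direct test, in 166 genes and 10 gene lists. Nav2 was higher than Scr in shZeb1_C and lower in shZeb1_D, a difference of -4.88 between the hairpins.

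Only 10 splits of 6 arrays exist for a pairwise comparison, too few for a share under 0.05. For shZeb1_C, 1 of 10 splits reached 185 genes (highest other 0) and 1 reached 9 lists (highest other 8). For shZeb1_D, 1 of 10 reached 165 genes (highest other 0) and 2 reached 11 lists (highest other 11). Between the hairpins, 2 of 10 reached 166 genes and 3 reached 10 lists (highest other 10). The split of shZeb1_C 10, shZeb1_C 11 and shZeb1_D 13 from the rest called 1526 genes, several times the real count, which points to a structure of the samples: it follows the array sets described below, and with these as a covariate the hairpins differed in 700 genes. Of 100 drawn splits of all 9 arrays, 2 reached the 162 genes of the mean comparison (highest other 208, a split that kept the 3 Scr arrays together). The 42 shared genes were reached by 1 split (highest other 40), so both shares lay under 0.05. These splits treat the arrays as independent samples, which the labels do not establish. They therefore cannot exclude chance differences between the 3 cell populations. For the 9 lists of the mean comparison 22 of 100 splits gave as many (highest other 12), so chance was not excluded.

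Blocks of neighbouring genes shifted together. All 12 blocks found in the first array set kept their sign in the second (100%; shZeb1_D has 1 array in the first set, Scr and shZeb1_C 1 each in the second), against the array sets as the cause. In the held-out set a median of 81.4% of the genes of a block moved its way, consistent with a copy number difference between the transduced populations, but no DNA was measured here and regional regulation would look alike. Blocks held 27.7% of the 307 genes called against Scr (23.2% and 37.6% per hairpin under the looser rule). Calls outside the blocks found are thus not direct effects of their shifts. For calls inside, the share counts location only and does not show that a shift caused them. The median size of a called log2 fold change was 1.71 in shZeb1_C and 1.58 in shZeb1_D. The largest block shift was -0.74. Runs too short for these rules, and effects of block genes on genes elsewhere, are not counted in this share.

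The arrays labelled shZeb1_C gave as many calls as shZeb1_D with little loss of Zeb1 mRNA. Of the genes called in shZeb1_C without 1 of its arrays, 88.9% to 92.4% differed between shZeb1_D and that held-out array in the direction opposite to their change. For these genes, this argues against a response in proportion to Zeb1 mRNA. However, selecting on shZeb1_C favours genes that differ in that population alone, and the held-out array comes from it. The test therefore says nothing on a proportional response of other genes. Genes called in shZeb1_D were not tested in this way. The test takes Zeb1 to have fallen less in shZeb1_C, a difference that itself missed the threshold, and protein was not measured. Of the 42 shared genes, 23.8% (exact 95% interval 12.1 to 39.4) lie in blocks shifted with both hairpins, against 2.86% of tested probe sets. These blocks were found from the same fold changes, so an excess over 2.86% is built in. The blocks all shifted down, so that 9 of the 10 genes fell also follows from how they were defined. The interval takes genes as independent, although most of the 10 lie on chromosome 2. Altered chromosomes of the control population cannot be told apart from hairpin effects as the cause of the shared changes, rises included, because both comparisons use the same Scr arrays.

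Arrays Scr 8, shZeb1_C 12, shZeb1_D 14 and shZeb1_D 15 deviated together from the other 5, on a component with 57.9% of the within-group variance. After quantile normalizing again it held 58.1%, against a difference in overall signal distribution as the cause, and its Spearman rho with mean expression across genes was -0.04, against a compressed signal range as the main cause. The interquartile range was 4.36 in shZeb1_C 12, against 4.54 and 4.48 in shZeb1_C 10 and 11. It was 4.25 and 4.18 in shZeb1_D 14 and 15, against 4.46 in shZeb1_D 13. Scr 8 (4.56) lay between Scr 7 (4.35) and Scr 9 (4.63). A partial role of a compressed range is therefore open. No label names a batch, and no biological explanation was tested.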

How the results depend on the processing

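The array sets and the removal of shifted blocks were chosen after seeing the data, the other settings before. No paired analysis was possible because the groups share no replicate numbers. No result changed sign while called, but of 129 calls of genes selected by the naming rule, besides Zeb1, 84 were lost in at least 1 leave-out of an array and 45 held whichever array was left out. They lost 69 calls without Scr replicate 9, 66 without shZeb1_D replicate 15, 16 to 39 without each other array, 42 with only the arrays compared, 94 and 20 in the second and first array sets, and 0 to 10 under other settings; the cause of each change was not tested unless stated. Counts are given for shZeb1_C, shZeb1_D, the mean of both, shZeb1_D against shZeb1_C, and both hairpins alike, where the main values were 185, 165, 162, 166 and 42. Leaving out single arrays gave 43 to 214, 14 to 213, 16 to 219, 49 to 162 and 7 to 40. Array weights gave 572, 1076, 639, 833 and 197. The array sets as a covariate gave 875, 772, 804, 700 and 280; those sets come from the same values, so these p-values are too small. Both settings kept all main calls. The 5 arrays of the first set, with 1 of shZeb1_D, gave 424, 273, 379 and, for both, 92; the 4 of the second set, with 1 of Scr and 1 of shZeb1_C, gave 102, 0, 0, 77 and 0. In both sets, here and below, a lone array is assumed to vary like the other groups. An unadjusted p under 0.05 with a 2-fold change gave 530, 609, 420, 580 and 179. Using only the arrays compared gave 68 for shZeb1_D, 81 between hairpins and 13 for both. Without genes in shifted blocks, with fewer genes tested, counts were 119, 67 and 85 against Scr and 17 for both. Zeb1 in shZeb1_D kept its direction but lost its call with only the arrays compared and with an intensity trend (both -1.05), in the first (-0.98) and second (-0.96) array sets, and without single arrays (-1.13 to -0.98); adjusted p ran from 0.00906 to 0.381. In shZeb1_C Zeb1 was 0.05 in the second set. Lists called, in the same order of the 4 comparisons, were 9, 11, 9 and 10, and 0, 0, 0 and 2 with an estimated correlation, 4, 3, 2 and 4 with fry, 5 and 5 for shZeb1_D and the mean above the median level, 16 for shZeb1_C in the second set and 6 for shZeb1_D in the first. Low signal could hide changes in the dimmer probe sets, as no background measure was used here.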

Other observations

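The tests in this part were chosen before the data were examined, except those without block genes or with the array sets as a covariate. In shZeb1_C, camera also placed genes that restrain T cells higher: 2 of 32 rose, Lgals9 by 1.39 and Tnfsf10 by 1.58, and 3 rose and 1 fell when adjusted over the list alone. Mesenchymal genes were placed higher with 0 of 32 called. Hypoxia, respiratory chain and ribosome biogenesis genes were placed lower, with 0 falling, while Adm, a hypoxia-induced peptide, rose by 1.89. With an estimated correlation each of these calls was lost (adjusted p = 0.496 for T cell restraint, 0.565 for the respiratory chain and 0.547 for the other lists).

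In shZeb1_D, camera also placed histone, stress, DNA replication, JAK-STAT, hypoxia, podosome and ribosome biogenesis genes lower and B cell genes higher; Il4ra was the member of these lists that passed the test over all genes. With an estimated correlation these calls were lost (adjusted p = 0.151 for JAK-STAT and from 0.341 to 0.547 for the others). The B cell call was also lost without block genes (adjusted p = 0.0849) and the hypoxia call with the array sets as a covariate (adjusted p = 0.0563). All lists called lower had mean levels of 8.68 to 13.60, and the 2 called higher 6.53 and 7.16. Ribosomal proteins, at 16.33, were not called. Above the median level camera called 3 lists lower and 2 higher. The interquartile range of log2 signal was 4.18 to 4.46 in shZeb1_D arrays and 4.35 to 4.63 in Scr arrays. A narrower signal range in shZeb1_D was not tested as a cause. Between the hairpins, camera also placed podosome, interferon, histone, TGF-beta, NF-kB, stress and mesenchymal genes lower in shZeb1_D. Those calls were lost too (adjusted p = 0.0794 for NF-kB and from 0.132 to 0.648 for the others, with an estimated correlation), and the mesenchymal call also without block genes (adjusted p = 0.0572). In each called list the median, mean and test had the same sign. They differed for 4 lists not called in shZeb1_C and 5 in shZeb1_D, among them MHC class I, with a median of 0.10 and a mean of -0.07.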
